A study of Homo sapiens with 6 samples.

How the data were processed

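RNA of HEK293 cells, a line of human embryonic kidney origin, was hybridised to 6 Affymetrix Gene 1.0 ST arrays, which read each transcript cluster (a set of probes for 1 transcribed locus) with 1 biotin-labelled sample per array. Per the labels' protocols, total RNA was extracted with an RNeasy kit from HEK293 cells, and the submitters' processing notes name Partek software. The deposited values are linear intensities, 1 per transcript cluster and array, as their range shows: the lowest value per array lies between 3.73e-05 and 6.01e-05 and the highest between 8515 and 9795. The background correction, normalization and probe summary behind these intensities are not given in the sources used here. Each column of the deposited table was matched to its sample by accession, and no column belonged to another series.

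The groups follow the sample titles, 3 control and 3 treatment arrays. The labels disagree about the controls: the source field names a transient vector for the control cells and a Neo vector for the treatment cells, while the design text sets untreated cells against cells transfected with the empty plasmid pCMV9. The groups are therefore called control and treatment throughout. No label says whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

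The table held 33297 clusters. The platform annotation of 2016 gave 1 gene symbol to 19460 clusters, several to 1754 and none to 12083, and 19429 of the single symbols had an entry in the RefSeq gene table, which changed none of them. A gene with more than 1 cluster, as for 769 genes, was represented by the cluster with the highest mean over the 6 arrays, which left 18417 genes. In no such gene did some clusters pass the threshold and others miss it. Of the rows, 696 repeated an earlier row's values on all arrays, as happens for copies of 1 locus, and they were kept. No genome build is named in the sources used here, so no coordinates are given. Some listed genes, among them GBP1 and the HLA class I genes, had no cluster of their own symbol in the annotation and are not counted as measured.

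The design fixed before the data were examined assumed values on a log2 scale, with a plain log2 for linear ones. Because the deposited intensities approach 0, where a plain log2 stretches noise without bound, 16 was added to each intensity before log2. That choice was made after the range of the values was seen and before any test was run, and a plain log2 and offsets of 1 and 50 were added as alternatives. Fold changes are thus differences of log2(intensity + 16), treatment minus control, and they understate the change of dim clusters. Deposited detection calls were not used, so no cluster is called absent.

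Each cluster was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a block, two-sided, with Benjamini-Hochberg adjustment over all 33297 clusters and a threshold of 0.05 on the adjusted p. "Rose" and "fell" mean past that threshold. For 27 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the lists. camera with an estimated correlation and fry, whose directional test asks whether a list's genes move on balance one way and whose mixed test asks whether they change in either direction, were alternatives. Members that passed with an adjustment over the list alone are counted separately. The genes named are the 12 largest rises and up to 12 largest falls among passing genes whose groups did not overlap, 17 genes fixed in advance, and up to 4 members of each list with the lowest p. Genes named outside that rule are said to be so.

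The alternatives fixed before the data were examined were the replicate number as a block, quantile normalization, centring each array on its median, filters on dim clusters (those below the median mean intensity, or in its lowest quartile), a test of 1 cluster per gene, an intensity trend or a robust prior in eBayes, array weights, fold and p thresholds, the mean of a gene's clusters, and leaving out each array in turn. The fit for array weights stopped before it converged. The pipeline was tested on simulated data for this comparison, made from the means and residual variances of all 33297 clusters. In it 200 clusters were changed, 50 at each fold and all with a mean intensity above 50, so recovery of dimmer clusters was not tested. It called 0% of 1.5-fold changes, 16% of 2-fold, 78% of 4-fold and 96% of 8-fold changes, with 1 call among unchanged clusters, and 0 calls when nothing was changed. camera found a list of 40 genes moved by 0.3 on the log2 scale in 20 of 20 simulations and called 0 of 20 unmoved lists, at an unadjusted p under 0.05. Simulated clusters varied independently of each other, so false calls of lists whose genes move together were not tested. In the data the estimated correlation was 0.48 for the interferon-stimulated list and 0.429 for the histone list.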

Results

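Whole-transcript expression was measured on 6 arrays of HEK293 cells, 3 labelled control and 3 labelled treatment. The stated aim was to find which mediators accompany transfection with an empty plasmid that was associated with an anti-HIV effect. The labels disagree on what the control cells received (above). Median intensity per array lay between 77.2 and 84.2 over 33297 transcript clusters. Pearson's r between arrays on the log2(intensity + 16) scale was 0.956 to 0.985 within groups and 0.957 to 0.981 between groups. Treatment replicate 3 stood farthest from the rest, with a mean r of 0.963 with the other 5 arrays. The first principal component, with 37.8% of the variance, set that array apart, and the second, with 27.6%, had all 3 control arrays on 1 side and all 3 treatment arrays on the other.

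Antiviral genes of the interferon response rose together in the treatment arrays. OAS2, which makes the 2-5A activator of RNase L, went from an intensity of 30.1 ± 10.9 (SD, n = 3) to 1121 ± 340.2 (SD, n = 3), a log2 change of 4.6 ± 0.266 (SE). RSAD2 (viperin) rose by 4.59 ± 0.238, MX2, a dynamin-like inhibitor of HIV, by 4.45 ± 0.274, IFIT2 by 4.31 ± 0.242 and TRIM22 by 4.23 ± 0.251. Few genes fell: growth hormone 1 (GH1) and the decoy TRAIL receptor TNFRSF10D were the only 2 named genes with a passing decrease.

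In all, 124 clusters differed between the groups (limma, adjusted p under 0.05), 119 higher and 5 lower in the treatment arrays. They include 97 genes with a symbol of their own, 95 higher and 2 lower, and 71 of the 97 were in a list fixed in advance. All 124 changed by at least 2-fold, 53 by at least 4-fold and 7 by at least 16-fold. Without adjustment, 2430 clusters had p under 0.05, and the groups did not overlap in 14.6% of clusters, where chance gives 10%. The count was 40 with a plain log2, the scale of the design fixed in advance, and 58 with an offset of 1. It was 69 without control replicate 1 and 82 without treatment replicate 2. Of the 5 decreases, 0 kept their call with a plain log2, with an offset of 1 or without control replicate 1; 1 kept it without treatment replicate 2 or at an adjusted p under 0.01, 2 without control replicate 2, control replicate 3 or treatment replicate 3, and 3 with an offset of 50. The decreases called with a plain log2 (3) and with an offset of 1 (2) were thus other clusters. An intensity trend in the variance prior kept all 5 and called 15.

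The other rises that completed the 12 largest were those of XAF1 (4.17 ± 0.276), an apoptosis regulator, IFI44 (4.11 ± 0.229), OAS1 (3.70 ± 0.241), MX1 (3.66 ± 0.241), CMPK2 (3.66 ± 0.232), APOL6 (3.62 ± 0.311) and IFITM1 (3.58 ± 0.266), a membrane protein that limits viral entry, each on the log2 scale with its SE. Limma's adjusted p for the 12 ran from 8.88e-07 for OAS2, RSAD2, IFIT2 and IFI44 to 2.96e-05 for APOL6, whose call alone among them was lost with a plain log2 (adjusted p = 0.082, the highest of its 19 alternatives). MX2 and XAF1 had control means under the offset, and although both passed under every alternative, their changes ran from 3.34 to 5.81 and from 3.08 to 5.50.

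**Figure D1:**
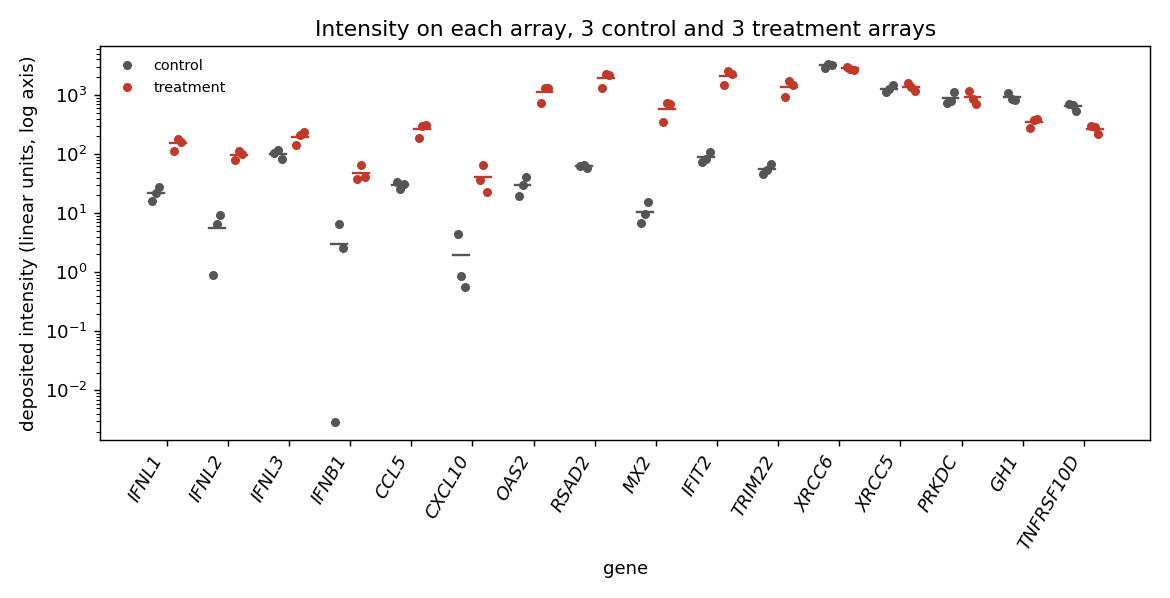
Deposited intensity (linear units, log axis) of 16 genes on each array, grey for the 3 control arrays and red for the 3 treatment arrays, with a bar at each group's mean. OAS2 went from a mean of 30.1 to 1121, XRCC6 had means of 3180 and 2820, and GH1 was lower in the treatment arrays (915 and 349).

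Of the 66 measured genes in the list of classical interferon-stimulated genes, 55 rose, 0 fell and 11 did not pass. The median log2 change over the 66 was 2.18. Beside those named above, IFIT1 went from 518 ± 60.7 to 3669 ± 348 (SD, n = 3), IFIT3 rose by 3.40 ± 0.196 on the log2 scale, the ubiquitin-like modifier ISG15 by 2.41 ± 0.227, and OASL by 3.18 ± 0.297, although the call of OASL ended with a plain log2 (adjusted p = 0.0598, the highest of its 19 alternatives). With an adjustment over the list alone, 65 of the 66 passed. IRF9 was among the members short of the threshold over all clusters (1.02 ± 0.227, adjusted p = 0.136), although it passed under 5 of 19 alternatives. The list passed camera with the preset correlation and with an estimated one (adjusted p = 0.00976).

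Among genes for the interferons themselves, 2 of 3 type III (lambda) interferons rose. IFNL1 went from 22.02 ± 5.76 to 152 ± 33.0 (SD, n = 3), a log2 change of 2.13 ± 0.222 (SE; limma, adjusted p = 0.000173), and IFNL2 from 5.61 ± 4.34 to 97.1 ± 16.1, a change of 2.40 ± 0.221 (adjusted p = 5.8e-05). IFNL3 gave 101 ± 16.6 and 198 ± 50.01, a change of 0.85 ± 0.229 that did not pass over all clusters (adjusted p = 0.346) but did over the list alone. IFNL2 and IFNL3 are near-identical in sequence, so probes may not separate them. Over the 3 genes the median change was 2.13, and the list passed camera with an estimated correlation too (adjusted p = 0.0223). With a plain log2, the adjusted p was 0.0618 for IFNL1 and 0.382 for IFNL2, the highest of their 18 alternatives, and for IFNL2 it was 0.0885 with an offset of 1. The log2 change of IFNL2 ran from 1.40 with an offset of 50 to 4.66 with a plain log2.

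Of 13 measured type I and II interferon genes, IFNB1 alone passed. It went from 3.02 ± 3.28 to 48.5 ± 15.4 (SD, n = 3), a log2 change of 1.75 ± 0.228 (SE; limma, adjusted p = 0.00148), with every treatment array above every control array. That call ended with each other offset (adjusted p = 0.71 with a plain log2, 0.156 with 1 and 0.058 with 50) and with a plain log2 plus an intensity trend, and it held under the remaining 13 of 17 alternatives. Its log2 change was 0.88 with an offset of 50 and 7.01 with a plain log2. IFNK (0.61 ± 0.226, adjusted p = 0.63) and IFNA6 (0.44 ± 0.22, adjusted p = 0.698) did not pass. Over the 13 genes the median was 0.19. Dim clusters rose slightly as a class. The 360 olfactory receptor clusters, of genes not expected to be active in this line, had a median change of 0.119. Over all clusters the median was 0.0116. The interferon list was dim (median control intensity 8.74), so part of its median may be shared by dim clusters of any kind. The list's camera call (adjusted p = 0.00791) was lost with an estimated correlation (adjusted p = 0.232), without control replicate 1, and without the lowest quartile of clusters, a filter that removed IFNB1.

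Of 31 chemokines and cytokines, 4 rose, 0 fell and 27 did not pass. The T-cell attractant CCL5 went from 30.6 ± 4.17 to 268 ± 69.5 (SD, n = 3), the death ligand TNFSF10 (TRAIL) rose by 1.93 ± 0.238 on the log2 scale, and the CXCR3 ligands CXCL10 and CXCL11 by 1.62 ± 0.26 (limma, adjusted p = 0.00943) and 1.15 ± 0.211 (adjusted p = 0.0274). With an adjustment over the list alone, 7 passed. The calls of CXCL10 and CXCL11 each ended under 7 of 17 alternatives, among them leaving out any 1 control array, and their adjusted p reached 0.294 and 0.529. The call of TNFSF10 ended with a plain log2 and an offset of 1. Over the alternatives the log2 change ran from 0.79 with an offset of 50 to 4.86 with a plain log2 for CXCL10, from 0.48 to 9.65 for CXCL11 and from 1.18 to 2.97 for TNFSF10. A plain log2 thus gave the largest changes of these 3 genes and ended all 3 calls. The 31 genes had a median of 0.27, and the list's camera call was lost with an estimated correlation (adjusted p = 0.0501). These genes were dim as well (median control intensity 25.4), so the slight rise of dim clusters (above) may be part of that median.

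Of 30 genes in the list of nucleic acid sensors and their signalling partners, 9 rose and 21 did not pass. The RNA helicases RIGI (2.56 ± 0.207) and IFIH1 (2.45 ± 0.209, MDA5), DDX60 (2.44 ± 0.207) and the endosomal RNA receptor TLR3 (2.39 ± 0.219) had the lowest p, and the transcription factors IRF7 (1.67 ± 0.258) and IRF1 (1.13 ± 0.205) passed as well, all log2 changes with SE. The call of IRF1 ended under 9 of 19 alternatives and that of IRF7 under 4. The 30 genes had a median of 0.20, and camera's call of the list was lost with an estimated correlation (adjusted p = 0.0503). Of the 25 members outside the interferon-stimulated list, a subset formed after the data were seen, 4 rose, with an adjusted p of 0.00122 by camera with the preset correlation and 0.272 with an estimated one.

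The subunits of the DNA-binding complex Ku and its kinase did not pass. XRCC6, which encodes Ku70, gave 3180 ± 222 in control and 2820 ± 168 in treatment arrays (SD, n = 3), a log2 change of -0.17 with a 95% interval from -0.59 to 0.24. XRCC5 (Ku80) gave 0.11 (-0.35 to 0.56) and PRKDC, the DNA-PK catalytic subunit, 0.03 (-0.49 to 0.55). Of the 13 measured genes of this list, 0 passed limma over all clusters or over the list alone and 0 had an unadjusted p under 0.05, and NHEJ1 (-0.35 ± 0.211), DCLRE1C (0.33 ± 0.231) and APLF (0.28 ± 0.234) had the lowest p. Their median was 0.09 (camera, adjusted p = 0.952). The treatment arrays went opposite ways: relative to the control mean, the list's median was 0.346, 0.132 and -0.281 in replicates 1, 2 and 3. Control arrays ran from -0.181 to 0.189.

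Among 23 genes reported to restrict HIV, 9 rose, 0 fell and 14 did not pass, with a median log2 change of 0.69. TRIM22, MX2 and IFITM1 (above) and IFITM3 (2.72 ± 0.254) had the lowest p. The call of IFITM3 ended with a plain log2 (adjusted p = 0.0687, the highest of its 19 alternatives). With an adjustment over the list alone, 14 passed, and the list passed with an estimated correlation (adjusted p = 0.0223). This list shares 11 genes with the interferon-stimulated list, and 1 of its other 12 rose, with a camera adjusted p for those 12 of 0.00355 with the preset correlation and 0.272 with an estimated one. Of 14 HIV receptors and cofactors 0 passed limma and 1 had an unadjusted p under 0.05, the receptor CD4 (-0.71 ± 0.223, adjusted p = 0.522). CD4 was dim, with means of 26.4 in control and 9.57 in treatment arrays. Both lay within the range of the olfactory receptor clusters (95th percentile 51.2 in control arrays), so its signal cannot be told from background. The list's median was -0.14 (camera, adjusted p = 0.18). Relative to the control mean, its median was 0.0351, -0.00437 and -0.369 in treatment replicates 1, 2 and 3, so replicate 3, the array that stood apart, carried the decrease.

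Of 13 measured antigen presentation genes, 4 rose and 9 did not pass, with 9 passing over the list alone. The immunoproteasome subunit PSMB9 rose by 2.37 ± 0.313 on the log2 scale, the peptide transporters TAP2 and TAP1 by 1.51 ± 0.226 and 1.44 ± 0.228, and the MHC class I transactivator NLRC5 by 1.55 ± 0.238. All 4 calls ended without control replicate 1 and with a plain log2 or an offset of 1. Over the alternatives the log2 changes stayed positive, from 1.91 to 2.78 for PSMB9, 1.31 to 1.72 for TAP2, 1.23 to 1.66 for TAP1 and 1.27 to 1.75 for NLRC5. The 13 genes had a median of 0.92, and the list's call was lost with an estimated correlation (adjusted p = 0.0654). Of the 13 measured interferon receptor and JAK-STAT genes, the feedback protease USP18 (1.84 ± 0.195) rose and 12 did not pass, among them the inhibitor SOCS3 (0.88 ± 0.293, adjusted p = 0.563) and the kinase TYK2 (-0.43 ± 0.208, adjusted p = 0.696). These genes had a median of 0.05, and the list's camera call was lost with an estimated correlation (adjusted p = 0.176). It was also lost without the 2 members shared with the interferon-stimulated list (camera, adjusted p = 0.75). Of 22 NF-kB targets, IRF1 was the only one to rise, the adhesion molecule ICAM1 gave 0.62 ± 0.234 (adjusted p = 0.642), and the list did not pass (median 0.03, adjusted p = 0.297).

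**Figure D2:**
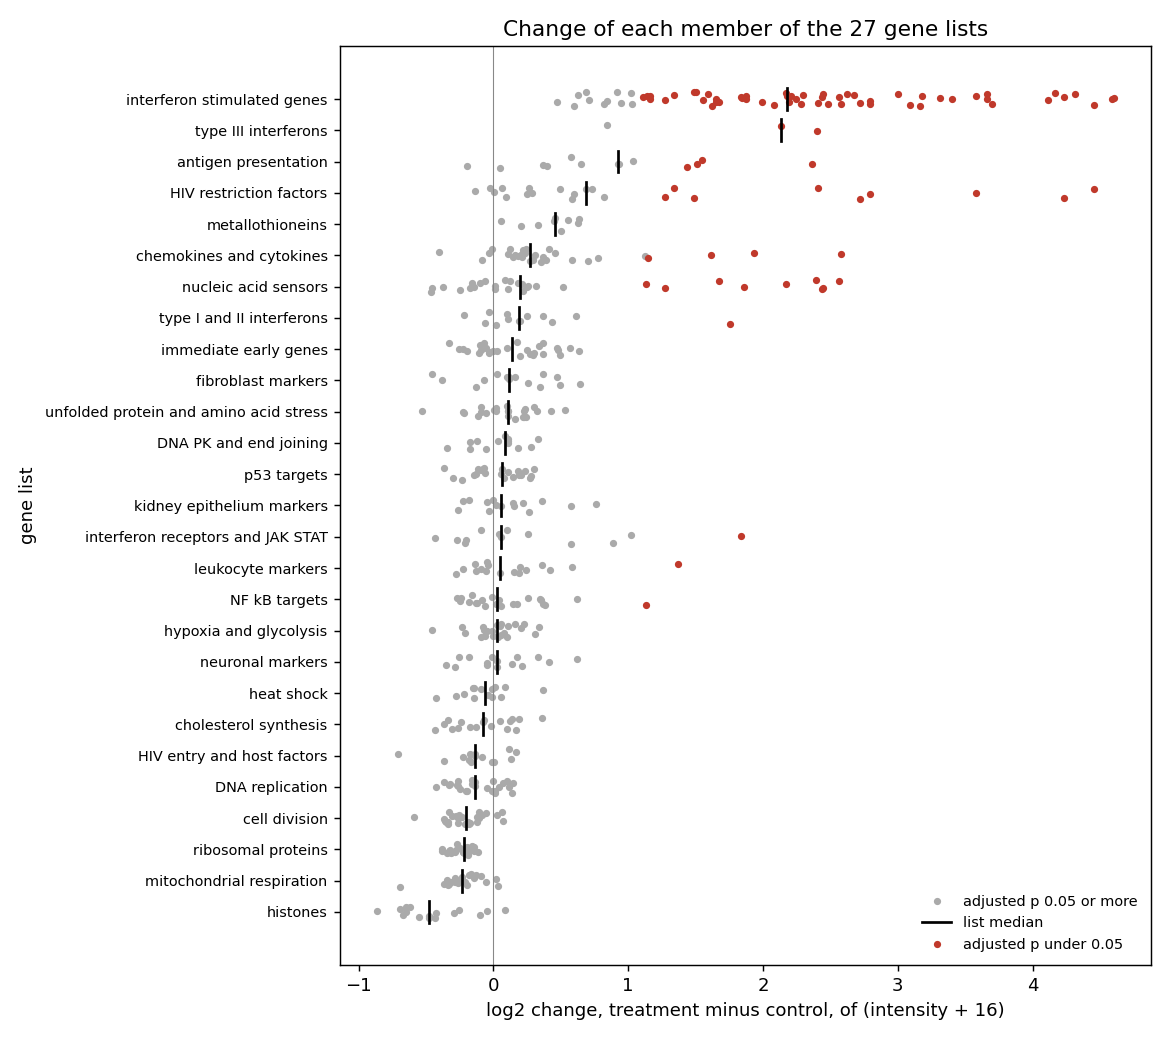
Log2 change of (intensity + 16), treatment minus control, of each measured member of the 27 gene lists fixed in advance, 1 point per gene and red where the adjusted p is under 0.05, with a bar at the list's median. The interferon-stimulated genes (median 2.18) and type III interferons (median 2.13) lie far to the right, and the histone genes have the lowest median (-0.47).

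The stress and growth lists held no gene that passed limma over all clusters. At an unadjusted p under 0.05 were 10 of the 16 histone genes, 6 of 9 metallothioneins, 5 of 28 immediate early genes, 2 of 24 unfolded protein and amino acid stress genes, 1 each among cholesterol, hypoxia, mitosis, DNA replication and respiration genes, and 0 among p53 targets, heat shock and ribosomal protein genes. Histone genes had the lowest median, -0.47 over 16 genes, with H2BC5 at -0.86 ± 0.22, H2BC8 at -0.69 ± 0.209 and H4C3 at -0.67 ± 0.206 (SE), and 6 of the 16 passed as decreases over the list alone. Their call with the preset correlation (camera, adjusted p = 2.13e-07) was lost with an estimated one (adjusted p = 0.239). The same held for ribosomal proteins (median -0.22, estimated adjusted p = 0.239), nuclear genes of the respiratory chain (-0.23, 0.113), metallothioneins (0.46, 0.23) and mitosis genes (-0.20, 0.496). The mitosis call was also lost without treatment replicate 3, the array that stood apart (median -0.02, camera adjusted p = 0.171). Relative to the control mean, the median of the mitosis genes was -0.487 in that array, -0.0909 in treatment replicate 2 and 0.0214 in treatment replicate 1, in log2 units.

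Lists without a camera call were those of p53 targets (median 0.06, adjusted p = 0.952), immediate early genes (0.14, 0.129), unfolded protein and amino acid stress (0.11, 0.396), heat shock (-0.07, 0.396), cholesterol synthesis (-0.08, 0.358), hypoxia and glycolysis (0.03, 0.983) and DNA replication (-0.14, 0.117). The stress-responsive factor ATF3 (0.63 ± 0.205, adjusted p = 0.546) had the lowest p of the immediate early genes. The lists of cell-type markers had no camera call either: fibroblast (0.11, 0.249), kidney epithelium (0.06, 0.311), neuronal (0.02, 0.781) and leukocyte markers (0.05, 0.17). Of the 17 leukocyte markers, the lysosomal protein CD68 rose (1.37 ± 0.246, limma, adjusted p = 0.0242), a call that ended under 8 of 19 alternatives, and 16 did not pass. Among the kidney markers, 1 passed over the list alone, the transcription factor PAX2.

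GH1, which encodes pituitary growth hormone, went from 915 ± 133 to 349 ± 63.9 (SD, n = 3), a log2 change of -1.36 ± 0.215 (SE; limma, adjusted p = 0.00834). TNFRSF10D, a TRAIL receptor without a working death domain, went from 641 ± 88.3 to 267 ± 38.9, a change of -1.22 ± 0.209 (adjusted p = 0.0169). Both calls ended without control replicate 1 (adjusted p = 0.102 and 0.159) and with a plain log2 or an offset of 1, and their adjusted p reached 0.247 and 0.266. That of TNFRSF10D also ended without control replicate 2, treatment replicate 2 or treatment replicate 3. The size of the changes moved less than the calls: over the alternatives it ran from -1.45 to -1.20 for GH1 and from -1.33 to -1.10 for TNFRSF10D. The other 3 clusters that fell had no gene symbol in the annotation used here. The largest called fall was that of a dim one among them, from 49.9 to 5.35 (-1.625 ± 0.278). Another gave 1068, 921 and 881 in the control arrays and 330, 486 and 476 in the treatment arrays. GH1 gave 1068, 850 and 827, then 276, 378 and 394, so their values were close.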

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

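The offset of 16, the other offsets and the plain log2 with an intensity trend were chosen after seeing the data. So were the lists without members shared with the interferon-stimulated list, whose remaining genes were not screened for induction by interferon. The plain log2 is the scale of the design fixed in advance. The count of 124 clusters (119 higher, 5 lower) fell to 40 (37 and 3) with a plain log2, and to 58 (56 and 2) with an offset of 1. Of the 124, 31 and 49 were called there, 0 of them among the 5 decreases. With a plain log2 and an intensity trend it was 126. An offset of 50 gave 100, with 3 lower. The intensity trend kept the 5 decreases and called 15, and an adjusted p under 0.01 kept 1. Leaving out 1 array gave 69 to 129 calls, 69 to 125 higher and 0 to 6 lower, lowest without control replicate 1 and next lowest without treatment replicate 2. The other alternatives left the count within 1.5 times, and none moved the median change of all clusters by over 0.1.

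The replicate number as a block gave 105 clusters (103 of them among the 124). Same-numbered arrays did not deviate together (r = -0.166, 0.0839 and -0.356), where other pairs gave -0.187 to 0.363. With 3 arrays a group, each group centred on its own mean, these values cannot show whether same-numbered arrays shared a batch. The block ended the calls of CXCL11 and IRF1 among the named genes and of no list. Of 38 called named genes, 20 passed under every alternative run, 18 lost the call under at least 1, and 0 changed sign. IRF9 gained a call under 5 alternatives, and SOCS3, H4C3 and MT2A under 1 each.

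With an estimated correlation, 10 list calls were lost at unchanged medians: type I and II interferons (0.19), receptors (0.0534), chemokines (0.27), sensors (0.20), antigen presentation (0.92), metallothioneins (0.46), mitosis (-0.20), histones (-0.47), ribosomal proteins (-0.22) and respiration (-0.23). fry's directional test lost 5 of these (type I and II interferons, receptors, metallothioneins, mitosis and histones), and its mixed test only mitosis, while the mixed test added NF-kB targets (0.029) and leukocyte markers (0.0519). Immediate early genes passed after quantile normalization (0.10) and with an offset of 50 (0.11), where DNA replication (-0.14) did too. Without the lowest quartile of clusters type I and II interferons were lost (0.11). Receptors were lost with a plain log2 or an offset of 1 (0.0519 and 0.052) and without shared members (0.0389). Leaving out 1 array gave medians of 0.145 to 0.213 for type I and II interferons (lost without control replicate 1), -0.198 to -0.078 for DNA replication (gained without control replicate 3) and -0.285 to -0.024 for mitosis (lost without treatment replicate 3); the receptors' median ran from -0.14 to 0.31 while camera kept them up. The cause of these changes was not tested. Low signal limits the size of change of IFNB1, IFNL2, CXCL10, CXCL11, TNFSF10, MX2 and XAF1, whose control means lay under the offset. The same holds below for APOL1 (control mean 9.49), GBP4 (7.52), CD274 (8.83) and the cluster of several guanylate-binding genes (6.1). Their changes were not followed over the alternatives.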

Other observations

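Of the tests below, those on olfactory receptors, growth hormone relatives and pituitary genes, and those on the lowest list medians, were chosen after the results were seen. The following genes were chosen after their values were seen. Outside the fixed lists, 26 called genes had a symbol of their own. The apolipoprotein L family, which lies in 1 gene cluster, had 3 of 6 measured members up: APOL6, APOL1 (2.33 ± 0.289, SE) and APOL2 (1.70 ± 0.221), while APOL3 gave 0.68 ± 0.207 without passing (limma, adjusted p = 0.507). Guanylate-binding proteins, interferon-induced GTPases, had 3 of 6 up, GBP3 (1.98 ± 0.292), GBP4 (1.72 ± 0.246) and GBP7 (1.26 ± 0.214), with GBP5 and GBP6 at 0.06 and 0.16 and GBP2 at 0.00496. A cluster that the annotation gives to several guanylate-binding genes together rose by 3.70 ± 0.274.

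The phospholipid scramblase PLSCR2 (1.42 ± 0.238) and the TRIM genes TRIM69 (1.16 ± 0.208) and TRIM56 (1.11 ± 0.196) rose too. With members of the fixed lists counted, 2 of 3 measured scramblases and 7 of 54 TRIM genes rose. Other called genes were UBA7 (2.35 ± 0.328), the activating enzyme for ISG15, the checkpoint ligand CD274 (PD-L1, 1.38 ± 0.219), the collagenase MMP13 (1.73 ± 0.222), RASGRP3 (1.92 ± 0.216), the complement inhibitor SERPING1 (1.34 ± 0.244) and the phospholipid flippase ATP10A (1.505 ± 0.223), all log2 changes with SE. Of the 55 interferon-stimulated genes that rose, 45 had their lowest treatment intensity in treatment replicate 1, 10 in replicate 3 and 0 in replicate 2. The list's median above the control mean was 1.85, 2.33 and 2.28 log2 units in treatment replicates 1, 2 and 3.

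The rise of the interferon-stimulated list was set against its technical explanations. Over other offsets and scalings between arrays its median stayed at 1.89 or above, and without each array in turn at 2.02 or above, so neither accounts for it. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, called 124 clusters, and the highest of the others called 1. Likewise only 1 split, the real one, gave a list median of 2.18, the highest other being 0.97. The 10 splits are too few for a share under 0.05. An effect of the transfected plasmid is the explanation the design names, and it was not tested apart from the grouping. If controls were untreated, as the design text says, plasmid and transfection procedure changed together and cannot be told apart here. If both groups received a vector, as the source field says, the comparison is between vectors.

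IFNB1, CXCL10 and CXCL11 rose from near 0, so noise of dim clusters was examined with 360 olfactory receptor clusters, genes not expected to be active in this line. With the offset used for its call, 0 of these rose as far as IFNB1. Their largest log2 rise was 0.74 and their median change 0.119. These 360 clusters cannot bound the extremes among all clusters, so such noise stays open. Outside them, the dim cluster without a symbol that fell most (above) gave -1.625. Another dim one without a symbol rose by 1.108. Whether those 2 changes were noise was not tested. Probes differ in background, however, and 33 of the 360 had a treatment mean at or above that of IFNB1, 42 at or above CXCL10, 9 at or above IFNL2 and 5 at or above IFNL1. The 95% interval of the IFNB1 change included 0 at 1 of the 3 other offsets, the plain log2 (-0.105 to 14.1), where control replicate 1 was close to 0, so the size of its change stays open. Of the clusters shared by several interferon alpha genes, that of IFNA14 and IFNA7 gave -0.14. The others examined gave 0.60, 0.75 and 0.77, each with every treatment array above every control array. Their unadjusted p was 0.0132, 0.00453 and 0.00677 (limma), and none passed over all clusters (adjusted p = 0.598, 0.457 and 0.522).

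GH1 fell, and of its relatives GH2, CSH2 and CSHL1 none passed limma over all clusters, but signal shared with the family stays open. The cluster without a symbol whose values lay close to those of GH1 (above) was not traced to a gene. The median change of GH2, CSH2 and CSHL1 was -0.12, with members on both sides of 0, and CSHL1 gave -0.44 with a 95% interval from -0.86 to -0.016, which reaches past -0.68, the bound set at 0.5 of the GH1 change. A wider pituitary programme stays open as well: the median of POU1F1, PRL, CGA and GHRHR was 0.15, but 3 of these 4 had control means within the range of the olfactory receptor clusters and so little room to fall. Whether plasmid sequence entered this signal was not tested, since vector maps and probe sequences were not used here. TNFRSF10A and TNFRSF10B, signalling TRAIL receptors, gave -0.09 ± 0.203 and -0.08 ± 0.224 where the decoy TNFRSF10D fell.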
